A study of Homo sapiens and Mus musculus with 9 samples.

How the data were processed

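The study applied enhanced UV crosslinking and immunoprecipitation sequencing (eCLIP) to the pregnane X receptor (PXR, gene NR1I2), a nuclear receptor that senses drugs and bile acids. Per the labels, RNA was crosslinked to protein with UV light, digested with RNase I, immunoprecipitated and sequenced. The 9 samples comprised LS174T cells (a human colorectal adenocarcinoma line) as a wild-type input, a wild-type PXR immunoprecipitate (IP) and an IP from PXR knockout cells, HepG2 cells (a human hepatocellular carcinoma line) as 1 input and 2 IPs, and liver of mice carrying human PXR as 1 input and 2 IPs. The HepG2 IPs used an antibody to the HA tag and the other IPs an antibody to PXR, per the labels. Per the submitters' processing notes the tools were cutadapt, BWA and MACS2 and the genome builds hg38 and mm10; versions and settings were not given in the sources used here.

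The deposited data analysed here were 4 peak lists, 1 for HepG2 IP, 1 for liver IP and 2 for LS174T. Each HepG2 and liver list stands for a group with 2 IP libraries, and whether the authors pooled them was not stated. The record assigns 1 LS174T list to the wild-type input library and the other to the wild-type PXR IP library. The names of these lists instead read wild-type IP and knockout IP, in the same order, and the peak names inside them read WT and KO. They are therefore called the WT-named and the KO-named list throughout, and no direction between genotypes, or between input and IP, is taken as settled. No list is tied to the knockout IP library in the record used here. No list carries values per library, so no spread between replicates could be estimated, and all tests run over peaks or genes, which are not replicates of a condition.

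For each peak the authors deposited a score, a fold enrichment (a ratio over the caller's local background) and the −log10 of a p-value and of a q-value, all taken as the authors' own values. The deposited score equalled 10 times the deposited −log10 q cut to a whole number in every row of the 4 lists. Fold, score and q were used here to describe, rank or filter peaks within a list. Peaks had been called separately for the plus and minus strand, per the peak names in the deposited files.

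Reads behind each peak were worked out here from the deposited fold and −log10 p. With a background λ, MACS2 gives fold = (n + 1) / (λ + 1) and p as the Poisson probability of more than n reads. All whole n were tried, and a solution was kept when p matched within 0.001 plus a small relative term, λ was a multiple of 0.02 within rounding (a window count whole within 0.01 plus the rounding of the fold), and the window held at least n reads. A step of 0.02 is what whole reads of the same library in a 10000 bp window give with 200 bp extension, and it limits the fold to 50. A unique solution was found for 5871 of 5884 peaks (99.8%). The other 13, all very deep, were solved without the whole-number condition and are approximate. On simulated peaks as numerous as each list, 1556 of 1557 were recovered for HepG2 and 2103 of 2103 for the WT-named list, with 0 wrong. The reads may include PCR copies, so intervals cover counting error only.

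Human peaks were assigned to genes by their summit with the GRCh38 RefSeq gene table, which has gene spans but no exons and was used without strand. A small RNA gene at the summit took precedence, then a pseudogene, then the shortest protein-coding or lncRNA gene. Exons, introns and UTRs, sequence composition and all mouse gene names need annotation not used here, so the planned feature shares became shares by gene type, and the planned comparisons of human genes with liver genes were not run. Liver peaks are given by mm10 position. Positions are 1-based.

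Lists were compared by overlap of at least 1 bp on the same strand, with 1000 random placements within annotated genes, and additionally within each peak's own gene. Shares carry Clopper-Pearson 95% intervals. Gene overlaps and 18 gene lists fixed before the data were examined were tested with two-sided Fisher's exact tests against 38340 nuclear protein-coding and lncRNA genes, with Benjamini-Hochberg adjustment over the 36 tests and 10000 draws of genes matched on 10 bins of length. An odds ratio with an empty cell had 0.5 added to each cell. Differences between HepG2 and the WT-named list were tested on genes with a peak in exactly 1 of the lists (exact binomial test, adjusted over 18 lists). In simulation of the HepG2 gene list test, 200 of 200 lists with 8 planted members were found and 8 of 200 empty lists fell under 0.05. For the overlap of HepG2 and WT-named peaks, 201 overlaps were found where 200 were planted.

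Named genes followed a rule fixed beforehand: the 15 protein-coding or lncRNA genes of highest fold in HepG2 and in the WT-named list, the 15 leading peaks of the KO-named list, NR1I2, and up to 4 members of each gene list. Its part on genes shared by all 3 tissues was applied to HepG2 and LS174T alone, and the small RNA sites, the genes with most peaks and the remaining sites of the KO-named list were named after their values were seen. Some genes that the rule takes are not reported here. Alternatives covered a stricter q, fold and overlap, merging, gene assignment, background genes and read minimum. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 were used.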

Results

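The WT-named LS174T list held 2103 peaks, the KO-named list 46, the list labelled HepG2 1557 and the liver list 2178. Peaks were short, with median widths of 213, 206.5, 200 and 201 bp. The reads recovered at the summit had a median of 11 in the WT-named list, 19 in the KO-named list, 9 in HepG2 and 13 in liver, and 783 HepG2 peaks (50.3%) rested on fewer than 10 reads. Distinct 10 kb windows around the peaks held 263254, 7684, 118920 and 441504 reads in the same order, which is a lower bound on the reads behind each list. The deposited fold enrichment reached 49.96, 48.8, 49.9 and 49.99, just under the limit of 50 that a background taken from the same library allows. No replicate values exist within a list, so differences below are not set against replicate spread.

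**Figure D1:**
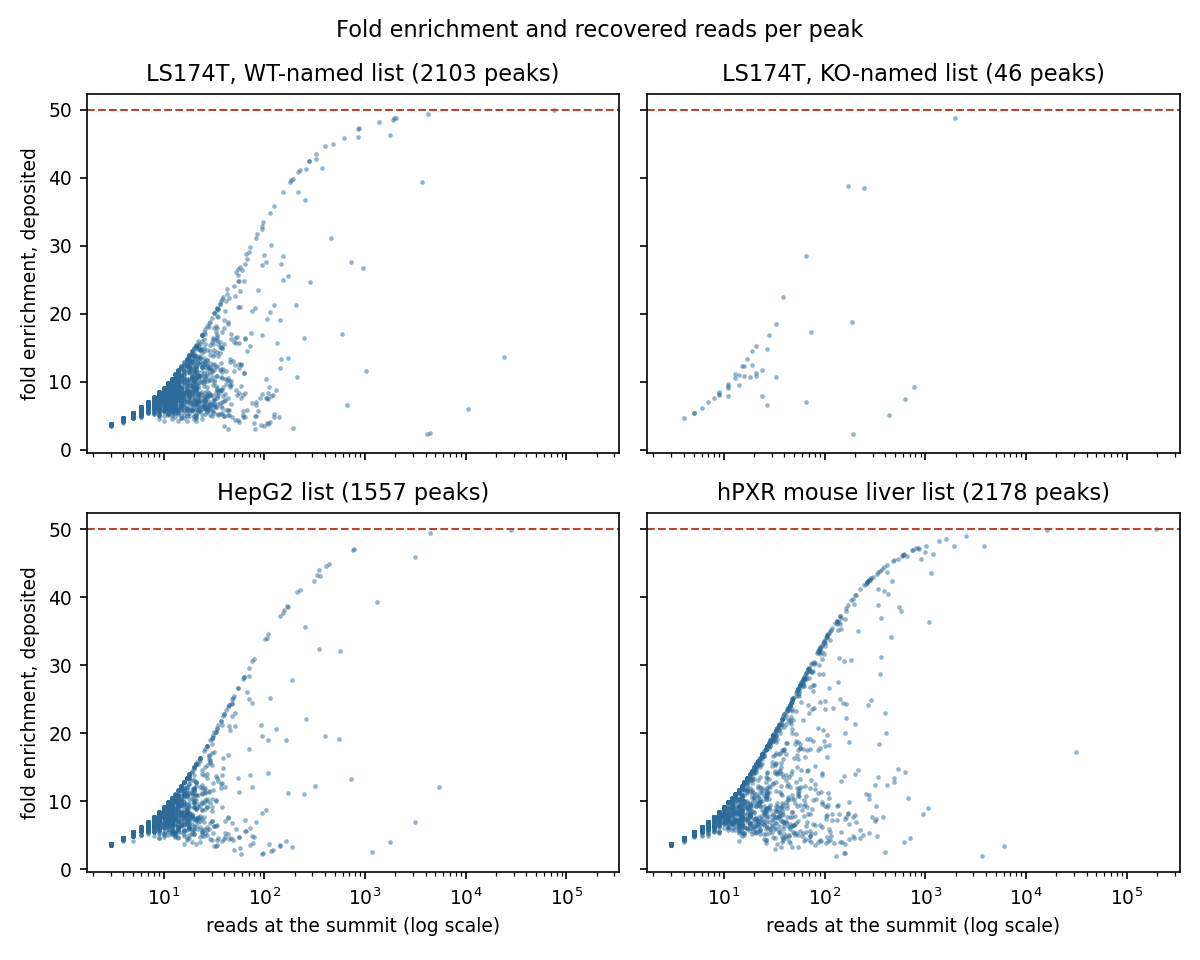
Each point is a peak, with the reads recovered at its summit on a log x axis and the deposited fold enrichment on the y axis, for the 4 lists. The dashed line is the fold limit of 50, which the deepest peak of each list approaches. Other deep peaks lie far below it, such as mitochondrial RNR2 in the WT-named list with 23957 reads and a fold of 13.6.

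NR1I2, which encodes PXR and is the gene removed in the knockout, lies on chromosome 3 from 119782101 to 119818487. None of the 3 human lists held a peak in it or within 5000 bp. These lists hold only called peaks, so its RNA level is not known, and the absence of a peak does not check the genotype of either LS174T list.

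The LS174T lists bear on whether RNA sites depend on PXR if the names of the lists hold, or on IP against input if the record holds. The KO-named list included sites in RPPH1 and RMRP, the RNA parts of RNase P and RNase MRP, the telomerase RNA TERC, the mitochondrial rRNAs RNR1 and RNR2, and the protein-coding genes RPLP1, RPLP2, RPS14, ACTG1, GAPDH, KRT8, KRT19, FTL and TMSB10. Of its 46 peaks, 44 (95.7%, interval 85.2 to 99.5%) overlapped a peak of the WT-named list, and the exceptions lay in mitochondrial ND2 and in the pseudogene RPS2P46. Among 36 nuclear peaks 35 were shared, against a mean of 0.013 in random placements (permutation p = 0.001, the smallest the placements can give). Moving each peak at random within its own gene gave 12.02 shared of 31 on average against 30 observed (permutation p = 0.001). The placement covered whole gene spans without regard to exons, so reads that gather in exons could also exceed it. In turn only 45 of the 2103 WT-named peaks (2.14%, interval 1.56 to 2.85%) met a KO-named peak.

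At the 44 shared sites the WT-named list held more reads at 42, with a median ratio of 7.48 (quartiles 2.82 and 16.8). Ratios are given by kind of RNA, and differences between kinds were not tested. For the 19 sites in protein-coding genes the median was 3.58 (range 0.585 to 470), with TMSB10 at 173 against 27 reads, RPLP1 at 118 against 33 and RPLP2 at 28 in both. It was 15.1 for RPPH1 (3718 against 246 reads), 51.6 for TERC and 84.2 for RMRP (1768 against 21). The deepest site, on a chromosome 22 scaffold of unknown position, held 76143 against 1984 reads, a ratio of 38.4. SYCP2L, a meiotic gene, stood at 4233 against 9 reads, and ZNF713 was the site with more reads in the KO-named list, 65 against 38. Each list has its own depth and no replicate, so these ratios compare 2 lists and not 2 conditions.

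**Figure D2:**
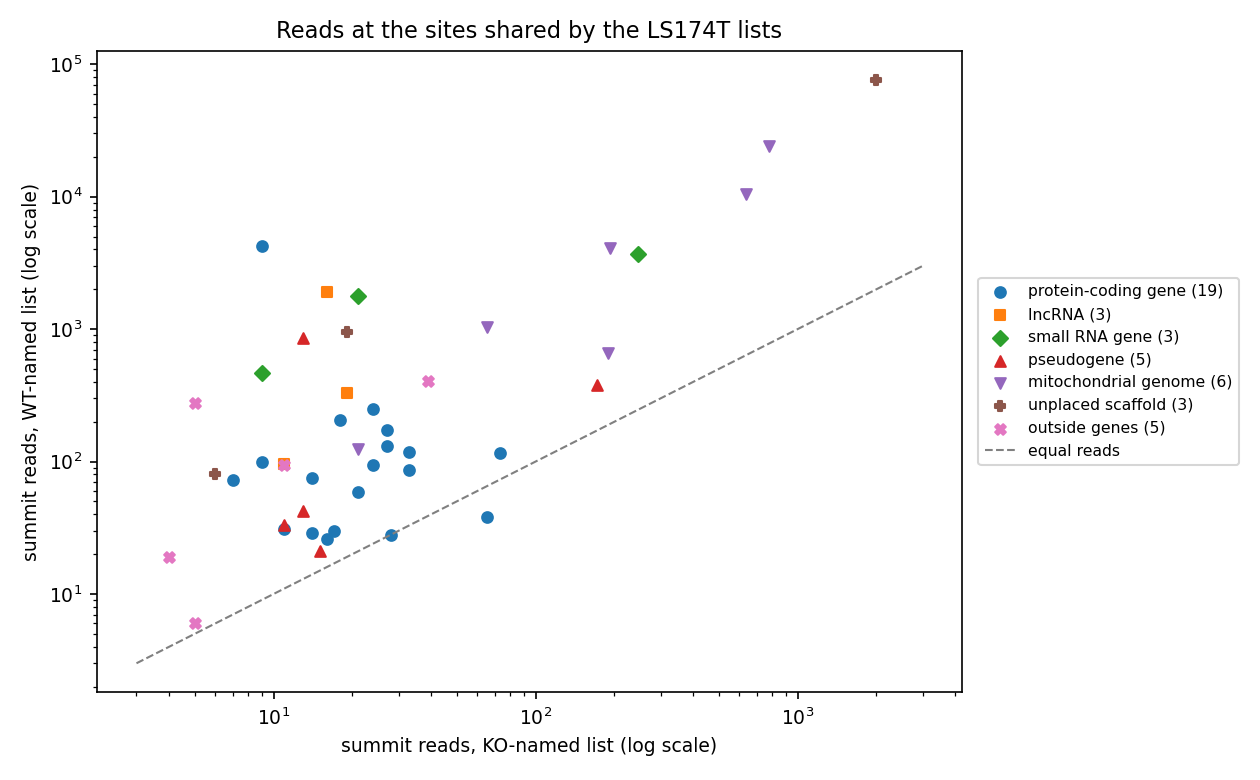
Summit reads at the 44 sites shared by the LS174T lists, KO-named on the x axis and WT-named on the y axis, both log scales, with symbols for the kind of gene and a dashed line at equal reads. Points above the line had more reads in the WT-named list, as 42 of 44 did.

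Among nuclear protein-coding and lncRNA genes, HepG2 and the WT-named LS174T list were led by largely the same sites. SYCP2L ranked first by fold among these genes in both, with 4408 reads and a fold of 49.5 in HepG2 at chromosome 6, 10887604 to 10887803, and 4233 reads at the identical position in LS174T. DNM3, which encodes a dynamin, held 435 and 873 reads, the lncRNA DANCR 312 and 1909, and ZNF773 109 and 2035, HepG2 first. Here as elsewhere genes were assigned without strand. A gene name therefore gives the place of a peak, and the reads may come from the opposite strand. The Wnt receptor gene FZD6 (226 and 73 reads), TRIM52-AS1 (172 and 35) and ZNF496-DT (80 and 94) were further shared sites. Of the 15 such genes of highest fold in HepG2, CDC42SE1 was the exception, with 76 reads and no peak in the WT-named list, and CWF19L1 (258 reads against 15), SPOCK3 (98 against 18) and LOC102724250 (256 against 70) led in LS174T. In each list 10 of the 15 leading peaks, SYCP2L among them, held all the reads of their window. Among other peaks in such genes with at least 50 reads, 5 of 40 did in HepG2 and 1 of 88 in LS174T. Lone stacks also reach the highest fold, by which the 15 were taken.

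In all, 600 of 1557 HepG2 peaks (38.5%, interval 36.1 to 41.0%) overlapped a WT-named peak and 601 of 2103 WT-named peaks (28.6%, interval 26.7 to 30.6%) overlapped a HepG2 peak. For 1531 nuclear HepG2 peaks the 580 shared exceeded the random mean of 0.423 (permutation p = 0.001, the smallest the placements can give). Moving each peak at random within its own gene still gave 101.5 shared of 1324 against 529 observed (permutation p = 0.001). These placements covered whole gene spans, introns included, and placement within exons was not run. The excess therefore cannot tell shared sites from reads that gather in the same exons in both lists. Sharing rose with depth, from 59 of 420 HepG2 peaks with 3 to 6 reads (interval 10.9 to 17.7%) to 82.2% of those with at least 50 reads (interval 72.7 to 89.5%). A HepG2 peak of few reads without a partner is therefore not shown to be specific to HepG2.

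By gene, 498 of the 1132 HepG2 genes also held a WT-named peak, where independent lists would share 41.7 of the 1411 WT-named genes. Genes matched on length shared 46.3 on average and at most 76 in 10000 draws (permutation p = 0.0001, the smallest the draws can give). Among them KRT18 held 110 and 125 reads, RPS2 75 and 86, the creatine kinase gene CKB 48 and 75, and SOX12 70 and 55. The lists contain no expression values, and abundant RNAs are more likely to yield a peak in any list.

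Cytoskeletal genes were among the most frequent carriers of peaks in both lists. In HepG2, 17 of 34 members had a peak against 1.00 expected (odds ratio 33.4, Fisher's exact adjusted p = 9.17e-17), and in LS174T 21 of 34 (odds ratio 42.9, exact adjusted p = 4.66e-21). The epithelial keratins KRT8 (164 reads in HepG2, 205 in LS174T) and KRT19 (72 and 146), and the actin regulator CFL1 (56 and 49), are examples. Chaperone genes had peaks in 14 and 15 of 32, led by fold by HSPB1 in HepG2 (263 reads) and the protein disulfide isomerase P4HB in LS174T (38 reads), where HSPA5 held 46 reads. Glycolysis genes had peaks in 8 of 22 in HepG2 and 12 of 22 in LS174T. Among these the glucose transporter SLC2A1 held 17 and 100 reads and GAPDH 38 and 251. RNA-binding and splicing factors were hit in 14 and 20 of 50, with HNRNPD at 21 and 18 reads, and translation factors in 9 and 16 of 38, with PABPC1 at 33 and 56 reads. Long noncoding RNAs of the nucleus and snoRNA hosts were hit in 8 and 10 of 28. GAS5 held 105 and 111 reads and SNHG1 26 and 31. All of these groups passed the exact test with adjusted p of at most 2.64e-06 in both lists.

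Ribosomal protein genes had a peak in 50 of 87 in the WT-named list and 21 of 87 in HepG2. They were carried by LS174T alone in 31 and by HepG2 alone in 2 (exact adjusted p = 2.36e-06). RPLP1 held 118 reads in LS174T and 46 in HepG2, RPS20 45 and 9, and RPS12 57 and 11. Histone genes went the other way, with 43 of 79 in HepG2 and 26 of 79 in LS174T, 19 in HepG2 alone and 2 in LS174T alone (exact adjusted p = 0.00199). H2AC20 held 32 reads in HepG2 and 20 in LS174T, H2AC12 30 and 20, and H3C7 had 28 reads in HepG2 and no peak in LS174T. Histone and ribosomal protein genes have near-identical copies, and the assignment of reads among them is uncertain.

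Colon epithelium genes had a peak in 15 of 30 in the WT-named list (odds ratio 26.4, exact adjusted p = 1.36e-13) and in 3 of 30 in HepG2, TFF1, EPCAM and CDH17 (odds ratio 3.66, exact adjusted p = 0.0799). The HepG2 count passed the test with −log10 q of at least 5 (exact adjusted p = 0.0345) and with at least 10 reads (exact adjusted p = 0.0152). PHGR1 (40 reads) and the trefoil factor gene TFF3 (68 reads) had no HepG2 peak. The adhesion molecule gene EPCAM held 38 and 11 reads and TFF1 51 and 38, LS174T first. With 13 in LS174T alone and 1 in HepG2 alone, the exact adjusted p was 0.0110, but against the split of all other genes found in 1 list it was 0.0672.

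Secreted plasma protein genes, which hepatocytes transcribe at high levels, had no peak in HepG2 (0 of 48 against 1.42 expected, exact adjusted p = 0.503) or in LS174T (0 of 48, exact adjusted p = 0.509). Hepatocyte metabolism genes had a peak in 1 of 34 in HepG2, the metallothionein MT2A with 12 reads. In LS174T they had 6 of 34 (odds ratio 5.63, exact adjusted p = 0.00246), among them GSTP1 (47 reads), the ferritin gene FTL (73 reads) and MT1X (24 reads), which many cell types transcribe. Markers of other liver cells reached 3 of 36 in each list (exact adjusted p = 0.119 in HepG2 and 0.187 in LS174T), in HepG2 KRT19, EPCAM and ADGRE1. KRT19 and EPCAM also belong to the cytoskeleton and colon lists, and with −log10 q of at least 5 the HepG2 count passed (exact adjusted p = 0.0490).

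PXR's known transcription targets had a peak in 1 of 33 in HepG2, the P450 reductase gene POR with 10 reads (exact adjusted p = 1), and in 0 of 33 in LS174T (exact adjusted p = 0.713). PXR and its partner proteins had 5 of 25 in each list, with exact adjusted p of 0.00144 in HepG2 and 0.00315 in LS174T. The coactivator gene NCOA3 (26 reads) was found in HepG2, the chaperone gene HSP90AB1 (23 and 46 reads) in both lists, HepG2 first, and AHR (9 reads) and HNF4A (7 reads) in LS174T. HSP90AB1 and HSP90AA1 (15 reads in HepG2) also belong to the chaperone list. In LS174T this call did not hold for peaks of at least 10 reads (exact adjusted p = 0.119). Bile acid and lipid genes had 4 of 40 in HepG2 (exact adjusted p = 0.0429) and 5 of 40 in LS174T (exact adjusted p = 0.0227), led by fold by the desaturase gene SCD (35 and 25 reads), with 41 and 29 reads in the fatty acid synthase gene FASN, and neither held with length matching (permutation adjusted p = 0.162 and 0.0825). Cell cycle genes had 5 of 29 in each list (exact adjusted p = 0.00251 and 0.00596), among them MCM7, CDKN1A and CCND1. Nucleolar genes had 0 of 23 in HepG2 and 5 of 23 in LS174T (exact adjusted p = 0.00246), including NCL and NOLC1, a call lost for peaks of at least 10 reads (exact adjusted p = 0.471). Genes of the m6A machinery had 0 of 19 in HepG2 and 1 of 19 in LS174T, YTHDF1 with 4 reads (exact adjusted p = 1 and 0.592).

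**Figure D3:**
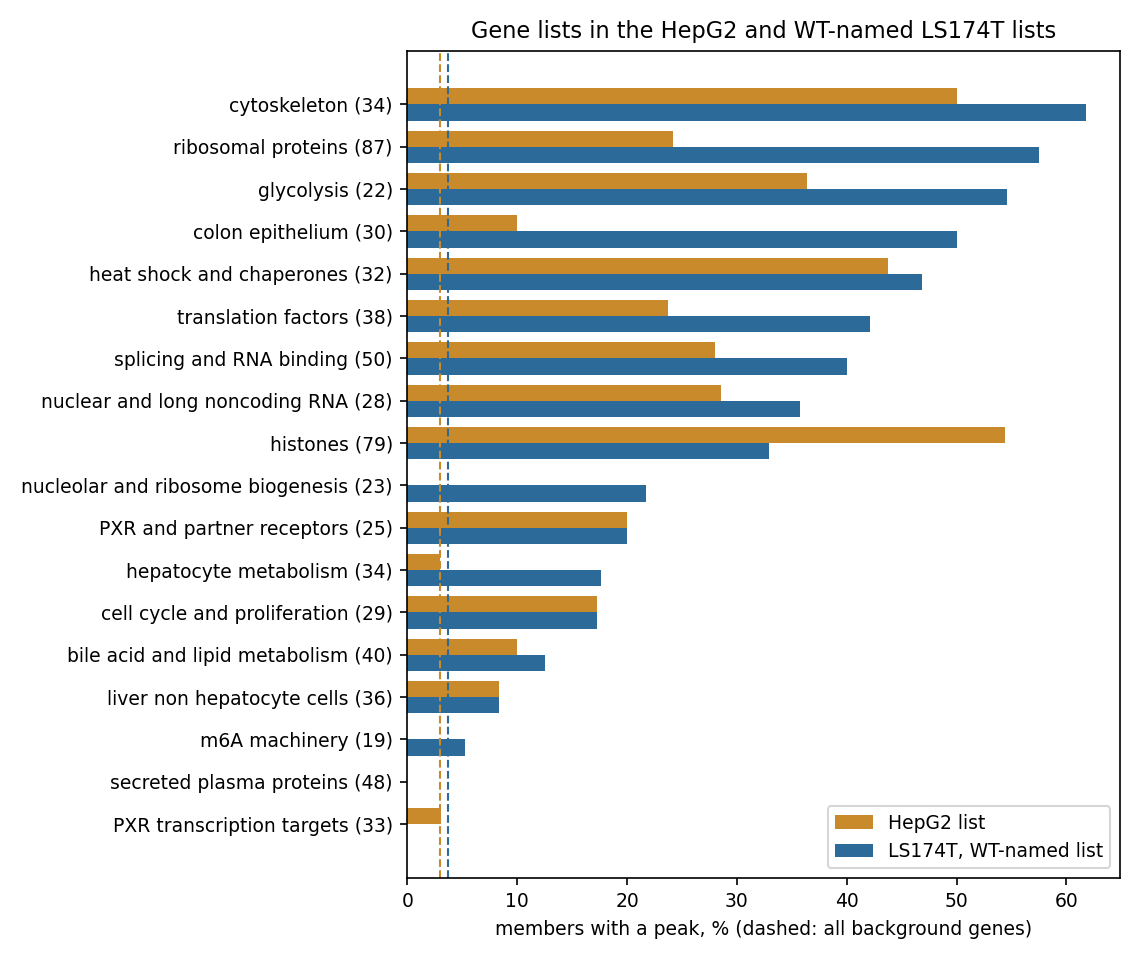
Share of each gene list's members with a peak, in percent, for HepG2 and the WT-named LS174T list, with the number of members in parentheses. Dashed lines mark the share of all background genes, 2.95% in HepG2 and 3.68% in LS174T.

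Protein-coding genes held 69.7% of HepG2 peaks (interval 67.3 to 72.0%) and 80.7% of WT-named peaks (interval 79.0 to 82.4%), and places outside annotated genes 13.3% and 4.90%. Both shares differed between the lists, with Fisher's exact adjusted p of 5.43e-14 and 3.29e-18 over 8 gene types. LncRNA genes were more frequent in HepG2 (172 of 1557 peaks against 136 of 2103, exact adjusted p = 2.61e-06) and pseudogenes less (3.79% against 6.04%, exact adjusted p = 0.00453). Small RNA sites ranged from 14 reads (SNORD133) upward in HepG2, with a median of 37.5, and from 8 reads (SCARNA2) upward in LS174T, with a median of 397. SCARNA28 held 1957 reads in LS174T and 51 in HepG2, SCARNA17 722 and SCARNA9 482 in LS174T, and RMRP 3179 and RPPH1 1321 in HepG2. NEAT1 carried 7 HepG2 peaks, MALAT1 6 and GAS5 5, whereas APP, ENO1, FAT1, PIGR and SPTBN1 carried 7 each in LS174T. In all 93 HepG2 and 284 WT-named genes carried 2 or more peaks.

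In liver of mice with human PXR the highest site lay on chromosome 2 (mm10, 90394970 to 90395190, minus strand), with 193871 reads. Further high sites on chromosome X (87238360 to 87238585, 16151 reads) and chromosome 18 (73533279 to 73533538, 2570 reads) held all the reads of their window. The mitochondrial genome carried 8 peaks, led by position 1146 to 2094 with 31100 reads. Peaks within 20 kb on a strand formed 1821 loci, of which 25 held at least 5 peaks, and 1655 (90.9%) held a lone peak. Those with most peaks were on chromosome 9 (103208761 to 103230249, 13 peaks) and chromosome 1 (71585579 to 71653100, 13 peaks), and chromosome 5 (90460934 to 90474859) had 11 peaks with up to 485 reads. Their genes are not named here, and no comparison with the human lists was made.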

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

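The thinning, luminal breast and amplified-region tests were set out before their results were seen, and the other tests of explanations in this part were chosen after. In 4 places the reading of a test was also changed after its result was seen, and each is named where it occurs. Peaks outside annotated genes made up 13.3% of the HepG2 list and 4.90% of the WT-named list, and peaks on scaffolds (random, unplaced and alternate sequences) 1.03% and 0.666%, above the 0.193% and 0.143% that a count of 0 allows, which says only that such peaks occur. Members found in exactly 1 of the lists differed between HepG2 and LS174T for ribosomal protein genes (adjusted p = 2.36e-06) and histone genes (adjusted p = 0.00199), each by an exact test of the difference, and both calls held against the split of all other genes found in 1 list, a test chosen after the result was seen (adjusted p = 7.16e-05 and 5.35e-05). For colon epithelium genes the exact test gave an adjusted p of 0.0110, but against that split the call was lost (adjusted p = 0.0672).

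The KO-named list had 46 peaks against 2103. Thinning the WT-named reads by 21.2, the ratio of window reads at the mitochondrial rRNA RNR1, left 63.9 peaks on average (95% of 1000 thinnings between 57 and 71.0). The mean was within the 1.5 times set beforehand, and the upper end was beyond it. A peak counted as left when its −log10 p was at least 7.59, the lowest value in the KO-named list itself. A looser cutoff, which could leave more peaks, was not run. By that factor and cutoff lower depth could account for most of the shortfall in number. The 19 shared protein-coding sites, taken for having a KO-named peak, had a lower median window ratio of 4.96. Thinning by a lower factor was not run, so the result holds for the RNR1 factor and that cutoff only. A common factor for every RNA is argued against by 29 of the 38 shared sites outside the mitochondrial genome, in distinct windows 20 above it (among them RPLP1, RPLP2 and FTL) and 7 below it of 36, where sites called from simulated reads under 1 factor gave at most 2 above and 0 below in 1000 draws, for counting error only, and thinning kept 22.7 of the 44 matched sites on average. Number and reads per site were first weighed as 1 pattern and were parted after these results, so depth alone is argued against for the pattern as first drawn. With 0 peaks at NR1I2 in the 3 human lists a list tied to the wrong library cannot be told apart from the labels, and loss of PXR stays open, untested.

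The HepG2 list had peaks at 0 of 48 plasma protein genes, and too few reads for abundant mRNAs is argued against by the 17 of 34 cytoskeleton genes with a peak (exact p = 1.44e-08). A candidate explanation is RNA of another cell type, luminal breast: 11 of 35 genes of a list without any gene already seen had a HepG2 peak, led by XBP1 (38 reads) and IGFBP5 (37 reads) and including ESR1 (9 reads), against 1.25 in length-matched draws (permutation p = 0.0001, the smallest possible), but 5 of 35 in LS174T also exceeded their draws (1.48, permutation p = 0.0174), and XBP1 and IGFBP4 are also transcribed in hepatocytes and 1 member, KRT7, is in the list of other liver cells. The test set beforehand also required an excess over LS174T, and this failed, with 10 genes in HepG2 alone and 4 in LS174T alone (exact one-sided p = 0.0898). An excess in 4 regions often amplified in a breast line also failed, with 5 of 280 against 3 of 160 (exact one-sided p = 0.678). It was tested only on peaks of at most 6 reads that held all the reads of their window. Deeper peaks in these regions were not compared, and the HepG2 peaks of the list members BCAS3, BCAS4 and ZNF217 lie there. By the conditions as written both results count against the idea; they were read as undecided only afterwards, because the intervals are wide, 41.9 to 91.6% for HepG2 alone among the 14 genes and 0.582 to 4.12% against 0.388 to 5.38% for the regions, and the 10 against 4 genes did exceed the split of all other genes found in 1 list, 624 in HepG2 and 909 in LS174T (exact two-sided p = 0.0271). For the HepG2 list a PXR-bound RNA set without plasma protein mRNAs stays open, untested. The liver IP list could bear on it, but its peaks were not assigned to genes here.

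Among protein-coding and lncRNA genes, largely the same sites led the HepG2 and WT-named lists by fold. Of the leading peaks of the 15 such genes of highest fold in HepG2, 12 were at most 205 bp wide, close to the 200 bp extension, against 11 of 40 other peaks in protein-coding and lncRNA genes with at least 50 reads (exact p = 0.000661), but narrow lone stacks also reach the highest fold, by which these 15 were taken, so stacked reads at 1 start, first read as borne out by this test, stay undecided. Whole read counts in the local window for 99.8% of peaks are in line with calling without an input control, so sites that are high in any library could have entered. Whether PXR binds them stays open, and 4 of the 15 also had a KO-named peak.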

How the results depend on the processing

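Read minimum, strand, own-gene placement and gene-assignment alternatives, and the comparison against genes outside a list, were chosen after seeing the data. Requiring −log10 q of at least 5 left 1033 HepG2, 1618 WT-named, 42 KO-named and 1634 liver peaks, raised the share of HepG2 peaks in the WT-named list to 43.8% and the share in protein-coding genes to 73.2%, and lowered the share outside genes to 9.97% in HepG2 and 3.96% in LS174T. The cause of these shifts was not tested. Peaks of at least 10 reads gave 42.2% shared. For colon epithelium the difference of -12 genes lost its call against genes outside the list; the cause was not tested. Of the other values of main results, 93 stayed on their side of the threshold or within their interval, or, for counts, within 1.5 times. Placing peaks within genes that carry a peak gave 128.2 times the random overlap, and within their own gene 5.21 times (2.497 times for the LS174T lists). Among single gene lists 201 values kept their side, 8 lost the call (bile acid and lipid, PXR partner and nucleolar lists) and 4 gained it (colon and other liver cells in HepG2, and luminal breast between the lists). Exon-only, transcript, coding-sequence, exon placement, strand-of-gene, flank and all liver gene alternatives were not run, because they need annotation not used here. No paired analysis was possible because each list stands for a group and carries no replicate number, and for the same reason no replicate could be left out. Sharing between HepG2 and the WT-named list was lowest for peaks of 3 to 6 reads in both directions, and the effect of depth on it was not tested.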

Other observations

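Some genes with several peaks in the HepG2 list are named here after their values were seen: GATA3, a transcription factor, with 3 peaks of up to 47 reads, the melanophilin gene MLPH with 4 peaks of up to 34 reads, the tight-junction gene CLDN4 with 3 peaks of up to 30 reads, and SPINT2 with 3 peaks of up to 30 reads. The WT-named list held 3 peaks in CLDN4, 2 in SPINT2 and none in GATA3 or MLPH. GATA3, MLPH, CLDN4 and SPINT2 had been seen before the luminal breast list was written. They were kept out of its test and add nothing to its result. IGFBP5 held 2 peaks of up to 37 reads and XBP1 2 peaks of up to 38 reads.

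The minus strand of the mitochondrial genome carried sites in each human list. Most reads lay at TRNY in HepG2 (565 reads) and in the WT-named list (288 reads). Positions 1 to 394 on that strand held 189 reads in HepG2, and positions 1 to 390 held 152 reads in the WT-named list. The KO-named list held 21 reads at CYTB.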
